A study of Mus musculus with 9 samples.

How the data were processed

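The 9 libraries were strand-specific TruSeq libraries of pooled RNA from mouse peritoneal macrophages sequenced on a NovaSeq 6000, per the labels. Cells were cultured for 1 h in RPMI 1640 medium before stimulation for 4 h, and each group of 3 libraries was made from pools of 3 RNA samples. The deposited values are FPKM per gene, fragments scaled by transcript length and by the mapped fragments of the library, and the submitters' processing notes name FastQC 0.11.2, STAR and StringTie, the last 2 without versions. The notes name the human build hg38, whereas the gene IDs are those of mouse, and 55154 of 55335 IDs were found in GENCODE M21, so no coordinates are given. Among them 3225 genes had no symbol, 156 shared a symbol with another entry, and 21918 were listed at 0 in all 9 libraries. An entry of 0 can be a failed estimate. All value columns were assigned to samples by name.

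FPKM values are not counts, and fragments were not recovered from them: only 39.3 to 45.7% of low values lay within 2% of a whole multiple of the commonest step or of its midpoint. The depths derived from that step are therefore estimates, and no counting error is given. Total FPKM per library ranged from 302126 to 363356. FPKM is relative to the fragments of each library, so abundant transcripts of a single class lower the values of all others.

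Genes with at least 1 FPKM in at least 3 libraries were tested (11721 genes). Values were taken as log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, all 9 libraries, group as the only term, 6 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. All tests were two-sided. The 41 gene lists for pathways and cell types were fixed before the data were examined, and the 40 with at least 3 tested members were compared with all other genes by camera, with a preset inter-gene correlation of 0.01 and adjustment over the lists. With an estimated correlation none of these calls held in any of the 3 comparisons. Splits of the libraries that mix the groups, given at the end, called as many lists or more with the preset correlation. Which lists the text describes was chosen after their results were seen.

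Named genes followed a rule fixed before the data were examined. It takes the 5 largest rises and falls per comparison among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between groups, leaving out predicted genes, pseudogenes and shared symbols. It adds 13 cytokine and polarization genes whatever their values, and up to 3 members of each described list with the smallest adjusted p plus 1 of the other direction. Other list members named singly, such as those that moved against their list, and the genes in the plots were chosen after their values were seen.

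Alternatives fixed beforehand were pseudocounts of 0.1 and 5, filters of any value above 0 and of 5 FPKM, TPM, median-ratio and quantile scaling, eBayes without trend and with robust fitting, only the groups compared, the replicate number as a block, a log2 change of at least 1, an estimated correlation and leaving out each library. Leaving out the 4 globin genes, testing protein-coding genes alone and median-ratio scaling with an estimated correlation were added after the data were seen. GENCODE M21 gave gene types, transcript lengths and GC content.

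The test was tried on simulated data with 50 changed genes per fold size among 11721. For log2 changes of 0.5, 1, 2 and 4 it recovered 24, 80, 96 and 100% in LPS+EtOH against LPS with 9 false calls, 26, 94, 100 and 98% in LPS+CPZ against LPS with 8, and 26, 86, 94 and 98% in LPS+CPZ against LPS+EtOH with 8. The simulated genes had independent noise and no shift of all values, and few changed, whereas most genes changed in the data. These shares therefore do not give the recovery or the false calls in the data. Preparation and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.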

Results

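Gene expression was measured by bulk RNA-seq in 9 libraries of mouse peritoneal macrophages, the resident phagocytes of the abdominal cavity. All cells received lipopolysaccharide (LPS), the bacterial cell wall component sensed by TLR4, at 1 µg/mL for 4 h. Of the 3 groups, LPS received nothing further, LPS+EtOH received 5% ethanol in addition, and LPS+CPZ received 100 µM of a compound that the labels call CPZ without spelling it out. Each group had 3 libraries, and each library was a pool of RNA from 3 samples. The labels do not say whether those samples were separate animals or cultures, so the p-values given here measure only the spread between pools. Unstimulated cells, cells given ethanol or CPZ without LPS, and a solvent control for CPZ were not analysed here, and every comparison is therefore between LPS-treated groups.

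Values are in FPKM and group values are means ± SD (n = 3 libraries). The commonest step between low values corresponded to 36000000, 39350000 and 31890000 fragments in the LPS libraries, 32850000, 32100000 and 27070000 in LPS+EtOH, and 28130000, 31580000 and 35350000 in LPS+CPZ. The number of genes at 1 FPKM or more was 11183 ± 85.0 in LPS, 8148 ± 189 in LPS+EtOH and 10353 ± 249 in LPS+CPZ. Across genes, which are not independent replicates, the correlation of log2 values was 0.975 to 0.989 between libraries of one group, 0.736 to 0.786 between LPS and LPS+EtOH, 0.8 to 0.839 between LPS and LPS+CPZ, and 0.858 to 0.885 between LPS+EtOH and LPS+CPZ.

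Transcripts of other cell types differed between the groups. The 4 adult globin genes, transcribed in red blood cell precursors, took 16.7, 11.5 and 29.4% of all FPKM in the LPS libraries, against 0.195 ± 0.025% in LPS+EtOH and 0.073 ± 0.026% in LPS+CPZ. The B cell gene Ms4a1, which encodes CD20, stood at 54.0 ± 12.8 FPKM in LPS, 1.22 ± 0.302 in LPS+EtOH and 7.65 ± 1.62 in LPS+CPZ. S100a9, an abundant calcium-binding protein gene of neutrophils that monocytes also express, stood at 3369 ± 551 FPKM in LPS, 33420 ± 2070 in LPS+EtOH and 3208 ± 99.4 in LPS+CPZ.

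**Figure D1:**
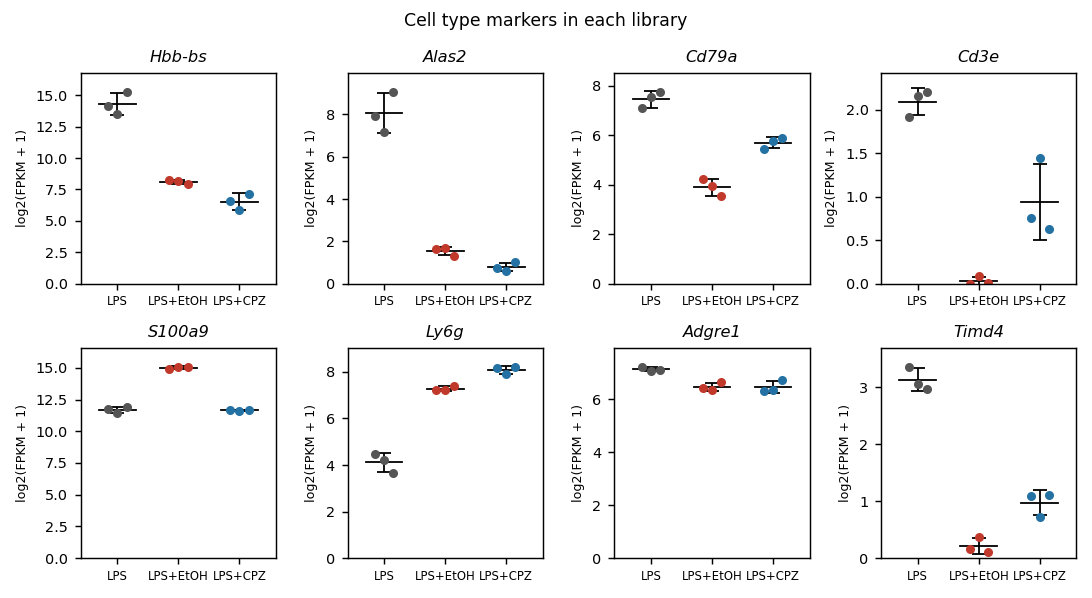
Each panel shows 1 gene, with log2(FPKM + 1) on the vertical axis, the 3 groups on the horizontal axis, points for libraries and bars for the mean and SD of the log2 values of the 3 libraries. The red blood cell genes Hbb-bs and Alas2, the lymphocyte genes Cd79a and Cd3e and the macrophage genes Adgre1 and Timd4 were highest in LPS, though Adgre1 was higher in LPS+EtOH than in LPS under median-ratio scaling (log2 change 0.518), S100a9 was highest in LPS+EtOH, and Ly6g was higher in both treated groups than in LPS.

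The comparison of LPS+EtOH with LPS asks how ethanol changes the LPS response, in a study whose title concerns M2b macrophages, a regulatory state marked by high IL-10. Il10 (ENSMUSG00000016529), the gene of that anti-inflammatory cytokine, rose from 104 ± 49.3 FPKM in LPS to 262 ± 39.4 in LPS+EtOH (log2 change 1.42 ± 0.27 SE, limma adjusted p = 0.000484). Tnfsf14, the gene of the TNF family cytokine LIGHT and a marker of M2b cells, rose from 5.99 ± 2.04 to 88.1 ± 18.2 FPKM (log2 change 3.70 ± 0.23, limma adjusted p = 1.82e-07). Cd86, which encodes a costimulatory receptor also used as an M2b marker, fell from 69.6 ± 14.7 to 5.09 ± 0.589 FPKM (log2 change -3.52, limma adjusted p = 7.52e-08). Il6 fell from 44.5 ± 22.3 to 0.53 ± 0.31 FPKM and Il12b, which encodes a subunit of IL-12 and IL-23, from 7.50 ± 2.02 to 0.157 ± 0.0318 FPKM. These are values of whole libraries, in which lymphocyte and neutrophil transcripts also differed. A change within macrophages therefore cannot be told apart from a change in cell composition, here or for the marker lists below.

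Of the 8 M2b markers, 7 could be tested. Il10 and Tnfsf14 rose, Cd86, Il6 and Il1b fell, and Tnf and Sphk1 did not pass the test, and camera did not separate the list from other genes (adjusted p = 0.449). Il1b stood at 3381 ± 859 FPKM in LPS and 2182 ± 507 in LPS+EtOH (log2 change -0.63 ± 0.22, limma adjusted p = 0.0215). Its call was lost without LPS replicate 1, without LPS+EtOH replicate 1 (log2 change -0.43 in each case) and without the filter on low values, and median-ratio scaling turned its direction (0.56). Tnf stood at 1745 ± 951 FPKM in LPS and 1037 ± 262 in LPS+EtOH (log2 change -0.65, limma adjusted p = 0.0944), a difference that passed the test without LPS replicate 2 (log2 change -0.99), under TPM and quantile scaling (-0.76 and -1.02) and with globin genes left out (-0.96), was -0.23 without LPS replicate 1, and had the opposite sign under median-ratio scaling (0.54). Sphk1 stood at 0.725 ± 0.107 and 1.00 ± 0.284 FPKM and passed the test as a rise under median-ratio and quantile scaling. Trpv1, the ion channel gene named in the study's title, was listed at 0 in all 9 libraries, and Ccl1, another M2b marker, had group means of 0.0311 ± 0.0278 FPKM in LPS, 0.0393 ± 0.0681 in LPS+EtOH and 0 in LPS+CPZ.

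**Figure D2:**
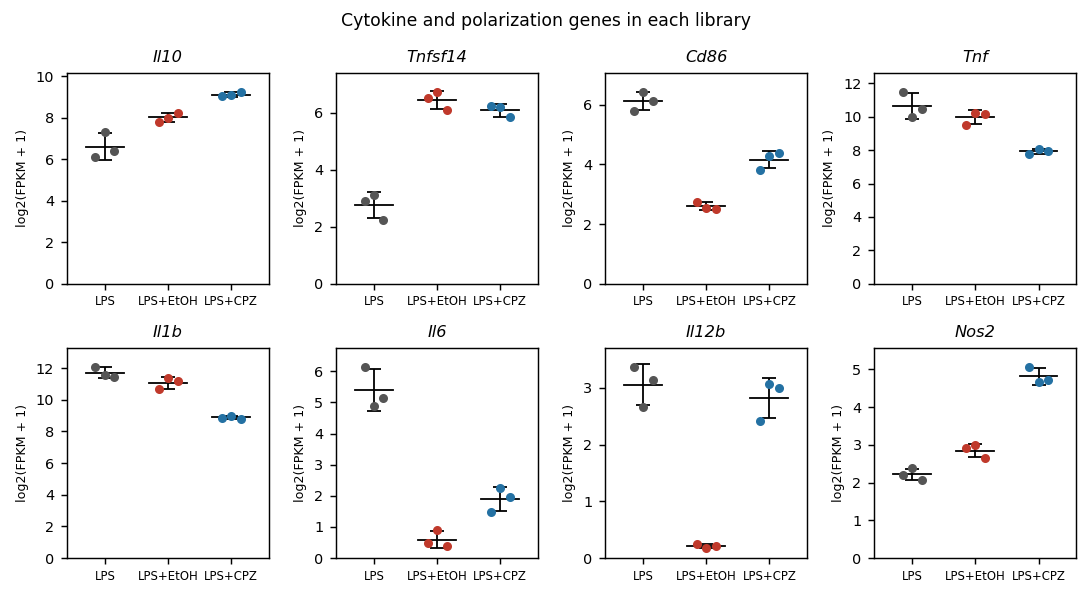
Each panel shows 1 cytokine or polarization gene, with log2(FPKM + 1) on the vertical axis, the 3 groups on the horizontal axis, points for libraries and bars for the mean and SD of the log2 values of the 3 libraries. Il10 and Tnfsf14 were higher and Cd86 and Il6 lower in both treated groups than in LPS, whereas Tnf and Il1b were lowest in LPS+CPZ, Il12b was lowest in LPS+EtOH and Nos2 was highest in LPS+CPZ.

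Among 19 tested inflammatory cytokines and mediators, 12 fell and Csf3, Ebi3, Nos2 and Osm rose in LPS+EtOH (camera adjusted p = 0.948), and under median-ratio scaling 7 fell and 5 rose. Of all 11721 tested genes 7566 fell and 2230 rose as deposited, so 12 of 19 is close to the general share. Under median-ratio scaling 4705 of all genes fell and 4673 rose. Csf2, the gene of the growth factor GM-CSF, fell from 36.3 ± 7.06 to 0.502 ± 0.282 FPKM, and Ptgs2, the inducible cyclooxygenase gene, from 822 ± 186 to 137 ± 5.02 FPKM. Ebi3, which encodes the shared subunit of IL-27 and IL-35, rose from 119 ± 6.26 to 341 ± 22.8 FPKM. None of the 32 tested interferon response genes rose and 26 fell (camera adjusted p = 0.162), with Ifit2 moving from 74.0 ± 18.8 to 1.72 ± 0.470 FPKM. Under median-ratio scaling 13 of them fell and 4 rose. Of 12 tested M2a markers, 7 fell, among them Fn1 (107 ± 37.4 to 0.415 ± 0.119 FPKM), Irf4 (251 ± 81.4 to 8.39 ± 2.28 FPKM), Retnla, Arg1 and Mrc1, while Chil3, Clec7a, Il4ra and Tgm2 rose (camera adjusted p = 0.746).

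Genes that restrain TLR signalling were mostly higher in LPS+EtOH: 16 of 18 rose, and Pdcd4 and Sigirr fell (camera adjusted p = 1.62e-07, adjusted p = 0.393 with an estimated correlation). Cish rose from 10.1 ± 0.705 to 46.9 ± 9.96 FPKM and Trib1 from 48.5 ± 11.8 to 195 ± 13.4 FPKM. In the list of NF-kB components and targets 15 of 28 genes rose and 9 fell (camera adjusted p = 0.000426, adjusted p = 0.617 with an estimated correlation), and 25 rose and 2 fell under median-ratio scaling. Sod2, which encodes mitochondrial superoxide dismutase, rose from 55.4 ± 10.7 to 145 ± 1.23 FPKM, while Ikbkb, the gene of the kinase IKK-beta, fell from 8.44 ± 0.713 to 0.981 ± 0.0945 FPKM. Of 25 immediate early genes 13 rose and Egr3, Klf4, Myc and Nr4a2 fell (camera adjusted p = 8.1e-05, adjusted p = 0.477 with an estimated correlation). Ier3 rose from 171 ± 28.7 to 1061 ± 89.1 FPKM, and Fos from 7.72 ± 0.394 to 22.0 ± 1.31 FPKM. Of 30 tested kinases of the MAPK cascades 8 rose and 14 fell as deposited (camera adjusted p = 0.188), whereas 20 rose and 6 fell under median-ratio scaling (camera adjusted p = 0.0356, adjusted p = 0.68 with an estimated correlation). Mapk13, which encodes p38 delta, rose from 1.41 ± 0.241 to 10.4 ± 0.590 FPKM, while Mapk11, which encodes p38 beta, fell from 7.64 ± 0.601 to 0.432 ± 0.0716 FPKM. In the same libraries the neutrophil genes described further on were higher and the lymphocyte genes lower. Some lists share members, so their results are not independent. Of the genes restraining TLR signalling, Tnfaip3, Bcl3, Nfkbia and Tnip1 are also in the NF-kB list and Zfp36 is an immediate early gene. Il10 is also an M2b marker and Dusp1 is in the list of MAPK phosphatases.

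Targets of the oxidative stress regulator NRF2 rose in LPS+EtOH, 20 of 23 passing the test (camera adjusted p = 8.56e-11, adjusted p = 0.477 with an estimated correlation). Hmox1, the gene of heme oxygenase-1, rose from 518 ± 30.1 to 3819 ± 521 FPKM. Ftl1, the ferritin light chain gene, which has near-identical pseudogenes, rose from 1752 ± 156 to 10150 ± 441 FPKM. Me1 alone fell, at 3.83 ± 3.45 and 0.428 ± 0.458 FPKM, and its log2 change of -1.51 was -0.96 without LPS replicate 1 and did not pass the test under median-ratio or quantile scaling. Lysosome and autophagy genes rose in 17 of 25 cases and fell in 4, among them Ctsa, Ctss and Npc2 (camera adjusted p = 3.26e-08, adjusted p = 0.393 with an estimated correlation). The cathepsin gene Ctsd rose from 264 ± 50.1 to 1630 ± 79.3 FPKM. Of 27 glycolysis and hypoxia genes 10 rose and Adm, Hk2, Ldha, Pdk1 and Pfkp fell (camera adjusted p = 0.00151, adjusted p = 0.617 with an estimated correlation), and 23 rose and 2 fell under median-ratio scaling. The hexokinase gene Hk3 rose from 15.6 ± 2.70 to 71.4 ± 7.13 FPKM.

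Ribosome biogenesis and ribosomal protein genes were mostly lower in LPS+EtOH. All 24 ribosome biogenesis genes fell under both the deposited and the median-ratio scaling (camera adjusted p = 0.000475, adjusted p = 0.874 with an estimated correlation), for example the RNA helicase gene Ddx21, from 80.4 ± 17.6 to 6.27 ± 1.12 FPKM. All 30 ribosomal protein genes fell as deposited, while 18 fell and 1 rose under median-ratio scaling (camera adjusted p = 0.00257, adjusted p = 0.874 with an estimated correlation). Ribosomal protein genes have many pseudogenes that can share their reads. Among 25 genes of the integrated stress response, a program of amino acid supply under translational stress, 18 fell and Ddit4, Ppp1r15a and Slc3a2 rose (camera adjusted p = 0.188). Under median-ratio scaling 15 fell and 7 rose (camera adjusted p = 0.0377, and 0.68 with an estimated correlation as well). Mthfd2, a mitochondrial one-carbon enzyme gene, fell from 61.0 ± 7.77 to 0.970 ± 0.158 FPKM (log2 change -4.97, limma adjusted p = 1.76e-08), and Psat1, a serine synthesis gene, from 27.5 ± 3.08 to 0.524 ± 0.1 FPKM.

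Neutrophil markers rose in LPS+EtOH, 12 of 13 passing the test with Mmp9 as the exception and 13 under median-ratio scaling (camera adjusted p = 8.91e-09, adjusted p = 0.393 with an estimated correlation). S100a8 rose from 995 ± 139 to 9141 ± 648 FPKM and Ly6g from 16.9 ± 4.79 to 156 ± 12.3 FPKM. Markers of B cells fell in 13 of 13 cases (camera adjusted p = 0.00129, adjusted p = 0.706 with an estimated correlation) and those of T and NK cells in 15 of 15 (camera adjusted p = 0.00358, adjusted p = 0.829 with an estimated correlation). The T cell receptor gene Trbc2 fell from 19.0 ± 1.00 to 0.0303 ± 0.0526 FPKM. All 6 red blood cell genes fell (camera adjusted p = 0.0726; under median-ratio scaling 0.00432, and 0.657 with an estimated correlation as well). Among 14 large peritoneal macrophage markers, 10 fell, including Timd4 (7.82 ± 1.29 to 0.162 ± 0.114 FPKM) and Prg4 (82.3 ± 13.1 to 1.11 ± 0.778 FPKM), while Cd9, F10, Itgam and Lrg1 rose (camera adjusted p = 0.824). Another gene ID carries the same symbol as Itgam, so the direction of Itgam is uncertain.

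The 5 largest rises by the fixed rule were Ngp, the gene of a neutrophil granule protein (log2 change 5.06 ± 0.93), Retnlg, which encodes a resistin-like protein (4.75 ± 0.31), the small GTPase gene Rhov (4.71 ± 0.33), the tight junction gene Cldn1 (4.62 ± 0.13) and the protease inhibitor gene Stfa2 (4.07 ± 0.21). Ngp stood at 4.62, 5.56 and 131 FPKM in the LPS libraries and at 568 ± 93.2 FPKM in LPS+EtOH. The 5 largest falls by that rule were Cxcl13, which encodes a chemokine attracting B cells (149 ± 76.6 to 0.141 ± 0.0956 FPKM, log2 change -6.93 ± 0.34), and the red blood cell genes Hba-a1, Hbb-bt, Alas2 and Hba-a2, with log2 changes of -6.60, -6.55, -6.51 and -6.40. Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so how their fragments were divided between them is uncertain.

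Of the 11721 genes tested with limma, 9796 changed between LPS+EtOH and LPS, 2230 higher and 7566 lower. The median log2 change of all tested genes was -0.82 on the deposited scale, and -0.01 after median-ratio scaling, under which 4673 genes were higher and 4705 lower. Quantile scaling gave 4160 higher and 4633 lower. The direction of some changes therefore depends on the scaling, and camera, which compares a list with all other genes, reads changes relative to it. The lists of M2b markers, M2a markers, chemokines, MAPK kinases, MAPK phosphatases, heat shock genes, cholesterol genes, p53 targets, inflammasome genes and mast cell markers had medians and means below 0 but a camera direction above the other genes. The TLR4 pathway list had a median below 0, and the TRP channel list a mean below 0, with the other values of each above. On the deposited scale the 2 groups did not overlap for 84.8% of genes, where chance gives 10%. The shift of all values can add to this share, which was not computed after scaling. In each list whose counts are given above for this comparison, the number of changed genes adjusted over the list alone equalled that over all genes tested.

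LPS+CPZ was compared with LPS to ask how CPZ changes the LPS response. Il10 rose from 104 ± 49.3 to 559 ± 38.2 FPKM (log2 change 2.52 ± 0.27, limma adjusted p = 1.67e-05), and Tnfsf14 from 5.99 ± 2.04 to 67.8 ± 9.93 FPKM (log2 change 3.33, limma adjusted p = 1.07e-06). Tnf fell from 1745 ± 951 to 245 ± 25.9 FPKM (log2 change -2.70 ± 0.34, limma adjusted p = 5.01e-05), Il1b from 3381 ± 859 to 473 ± 32.3 FPKM, Il6 from 44.5 ± 22.3 to 2.84 ± 0.998 FPKM and Cd86 from 69.6 ± 14.7 to 17.2 ± 3.53 FPKM. Nos2, the inducible nitric oxide synthase gene, rose from 3.67 ± 0.497 to 27.4 ± 4.50 FPKM (log2 change 2.6 ± 0.15, limma adjusted p = 2.74e-07). The largest rises by the fixed rule were those of Hspa1b and Hspa1a, near-identical genes of the inducible heat shock protein HSP70, with log2 changes of 6.90 ± 0.43 and 6.68 ± 0.42.

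Of 7 tested M2b markers, Il10 and Tnfsf14 rose, Cd86, Il1b, Il6 and Tnf fell, and Sphk1 did not pass the test except under median-ratio and quantile scaling, with the replicate number as a block and without LPS+CPZ replicate 3 (camera adjusted p = 0.993). The list's median log2 change was -1.96 and its mean -0.69. Among 19 inflammatory cytokines and mediators 14 fell and Nos2 rose (camera adjusted p = 0.0265, adjusted p = 0.816 with an estimated correlation). Csf2 fell from 36.3 ± 7.06 to 1.11 ± 0.429 FPKM and Il18 from 9.42 ± 0.214 to 1.19 ± 0.155 FPKM, whereas Il12b stood at 7.50 ± 2.02 and 6.22 ± 1.65 FPKM (log2 change -0.23 ± 0.21, limma adjusted p = 0.33). Interferon response genes fell in 29 of 32 cases, and in 30 when adjusted over the list alone (camera adjusted p = 2.35e-06, adjusted p = 0.803 with an estimated correlation). Ifit2 fell from 74.0 ± 18.8 to 2.56 ± 0.249 FPKM and Isg20 from 69.8 ± 9.26 to 11.7 ± 0.398 FPKM. Of 12 M2a markers Clec7a and Il4ra rose and Ccl22, Fn1, Irf4, Mrc1 and Retnla fell (camera adjusted p = 0.71). Arg1 stood at 3.94 ± 1.90 and 3.46 ± 3.11 FPKM and passed the test as a fall only without LPS+CPZ replicate 3, with a log2 change of -0.83 against -0.30 with all libraries.

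In the NF-kB list 20 of 28 genes fell in LPS+CPZ and Ikbkg and Sod2 rose (camera adjusted p = 0.00589, adjusted p = 0.803 with an estimated correlation). Rel, the gene of the NF-kB subunit c-Rel, fell from 214 ± 14.2 to 27.6 ± 5.10 FPKM, and the inhibitor gene Nfkbid from 173 ± 13.2 to 30.7 ± 2.29 FPKM. Ikbkg, which encodes the IKK subunit NEMO, rose from 9.02 ± 0.764 to 57.3 ± 10.3 FPKM. Of 30 MAPK cascade kinases 8 rose and 12 fell as deposited (camera adjusted p = 0.606), whereas 12 rose and 6 fell under median-ratio scaling. Map2k1, the gene of the kinase MEK1, rose from 33.8 ± 2.91 to 78.5 ± 2.85 FPKM, while Mapk11 fell from 7.64 ± 0.601 to 0.461 ± 0.0517 FPKM.

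Of 20 heat shock genes 17 rose and none fell in LPS+CPZ, and adjusted over the list alone 17 rose and 1 fell (camera adjusted p = 1.53e-08, adjusted p = 0.787 with an estimated correlation). Hsp90aa1 rose from 104 ± 11.3 to 598 ± 85.5 FPKM and the co-chaperone gene Dnajb1 from 14.7 ± 0.970 to 134 ± 37.6 FPKM. NRF2 targets rose in 20 of 23 cases, and in 21 when adjusted over the list alone (camera adjusted p = 1.04e-13, adjusted p = 0.514 with an estimated correlation). Hmox1 reached 13770 ± 2002 FPKM from 518 ± 30.1, and Gclc, which encodes the catalytic subunit of glutathione synthesis, 685 ± 86.2 FPKM from 44.6 ± 4.18. Glycolysis and hypoxia genes rose in 24 of 27 cases and Pfkp fell (camera adjusted p = 4.19e-15, adjusted p = 0.266 with an estimated correlation). The fall of Pfkp did not pass the test under median-ratio scaling. Tpi1, a glycolytic enzyme gene with processed pseudogenes, rose from 9.53 ± 0.397 to 135 ± 12.5 FPKM, and the phosphofructokinase gene Pfkl from 6.44 ± 0.362 to 88.5 ± 5.79 FPKM. Of 25 lysosome and autophagy genes 22 rose and 2 fell, among them Ctss (camera adjusted p = 6.63e-12, adjusted p = 0.266 with an estimated correlation). Npc1, a lysosomal cholesterol transporter gene, rose from 9.88 ± 0.870 to 82.3 ± 7.28 FPKM. The other leading rises were Ptgr1, a prostaglandin reductase gene (6.70 ± 1.92 to 316 ± 53 FPKM), Bnip3, a mitophagy receptor gene induced by hypoxia (1.78 ± 0.499 to 108 ± 13.1 FPKM), and Slc22a4, an organic cation transporter gene (2.88 ± 1.54 to 110 ± 11.1 FPKM).

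All 24 ribosome biogenesis genes fell in LPS+CPZ (camera adjusted p = 4.89e-06, adjusted p = 0.803 with an estimated correlation), with Nolc1 moving from 38.2 ± 11.2 to 6.56 ± 0.855 FPKM. Of 30 ribosomal protein genes 28 fell, 29 when adjusted over the list alone and 10 under median-ratio scaling (camera adjusted p = 0.0135, adjusted p = 0.901 with an estimated correlation). All 13 mitochondrially encoded transcripts fell (camera adjusted p = 0.0135, adjusted p = 0.816 with an estimated correlation), among them mt-Nd5, from 589 ± 101 to 218 ± 10.5 FPKM, and 12 fell under median-ratio scaling. All 13 also fell in LPS+EtOH (camera adjusted p = 0.188), but 2 under median-ratio scaling.

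Red blood cell genes fell in 6 of 6 cases (camera adjusted p = 0.00168, adjusted p = 0.803 with an estimated correlation), and Hbb-bt, Hba-a1, Hba-a2, Hbb-bs and Alas2 were the 5 largest falls by the fixed rule, with log2 changes of -8.21, -8.04, -7.84, -7.77 and -7.26. Of 13 B cell markers 12 fell (camera adjusted p = 0.00106, adjusted p = 0.803 with an estimated correlation). Ighm, the immunoglobulin mu gene, was the exception, with a log2 change of -0.09. T and NK cell markers fell in 14 of 15 cases (camera adjusted p = 0.00805, adjusted p = 0.816 with an estimated correlation), for example Lck, from 12.9 ± 2.83 to 1.87 ± 0.503 FPKM, and Cd28 rose, a call lost with globin genes left out. Of 13 neutrophil markers Lcn2, Ly6g, Retnlg and S100a8 rose and Csf3r, Cxcr2, Ltf and Stfa2l1 fell (camera adjusted p = 0.182). Under median-ratio scaling 4 rose and 2 fell. Ly6g rose from 16.9 ± 4.79 to 274 ± 31.1 FPKM, S100a8 rose from 995 ± 139 to 2752 ± 150 FPKM, and Cxcr2 fell from 11.4 ± 2.74 to 3.81 ± 0.705 FPKM.

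With limma, 8106 of 11721 genes changed between LPS+CPZ and LPS, 2432 higher and 5674 lower, and the median log2 change of all genes was -0.33. Under median-ratio scaling this median was -0.06, and 3351 genes were higher and 3806 lower. Quantile scaling gave 3441 higher and 4069 lower. On the deposited scale, with its shift of all values, the groups did not overlap for 72.9% of genes, where chance gives 10%. The lists of MAPK kinases, immediate early genes, brakes on TLR signalling, ER chaperones and integrated stress response genes had medians and means below 0 but a camera direction above the other genes, and the cholesterol list had a median below 0 only. Except where stated, the number of changed genes adjusted over the list alone equalled that over all genes tested for each list whose counts are given for this comparison.

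**Figure D3:**
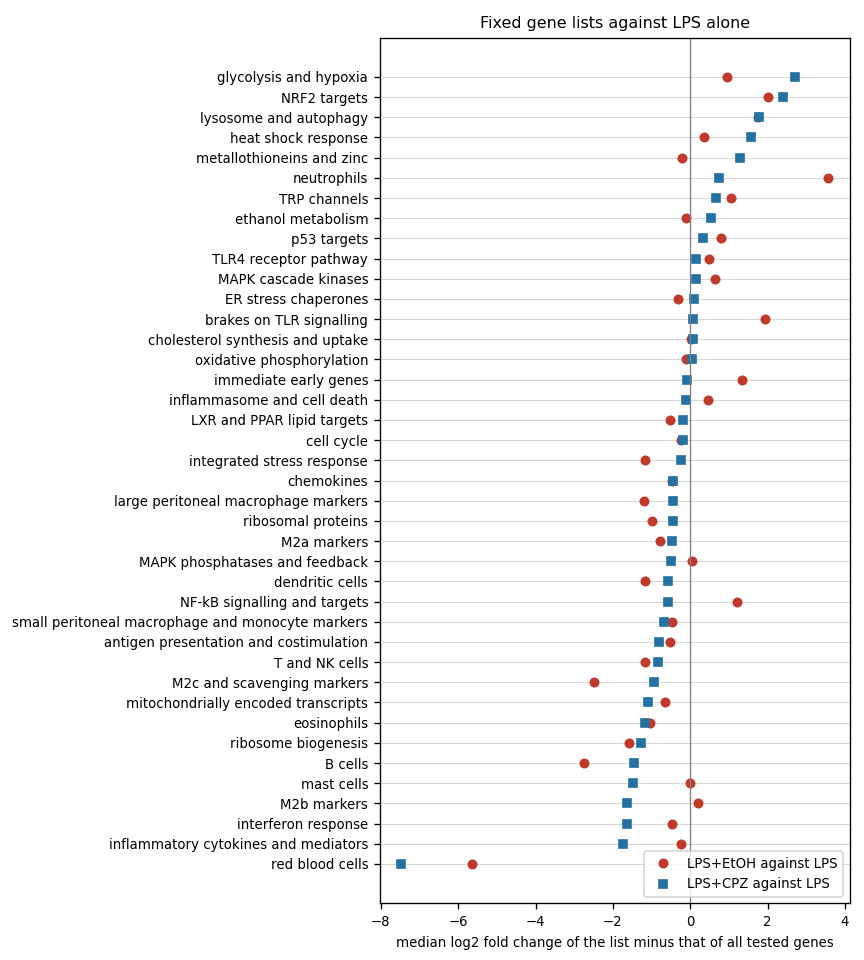
The horizontal axis is the median log2 fold change of a fixed gene list minus that of all tested genes, for LPS+EtOH against LPS (circles) and LPS+CPZ against LPS (squares), with 1 line per list. NRF2 targets and lysosome genes lay to the right in both comparisons and red blood cell genes far to the left, while the neutrophil list lay at 3.57 for LPS+EtOH and 0.74 for LPS+CPZ.

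The direct comparison of LPS+CPZ with LPS+EtOH tests the difference between the treatments. Tnf was lower in LPS+CPZ than in LPS+EtOH (245 ± 25.9 against 1037 ± 262 FPKM, log2 change -2.05 ± 0.34, limma adjusted p = 0.000264), as was Il1b (473 ± 32.3 against 2182 ± 507 FPKM, log2 change -2.18 ± 0.22). Il12b (6.22 ± 1.65 against 0.157 ± 0.0318 FPKM), Nos2 (27.4 ± 4.50 against 6.23 ± 0.822 FPKM) and Cd86 (17.2 ± 3.53 against 5.09 ± 0.589 FPKM) were higher in LPS+CPZ. Il10 was higher in LPS+CPZ (559 ± 38.2 against 262 ± 39.4 FPKM, log2 change 1.1 ± 0.27, limma adjusted p = 0.00328), but this did not pass the test under median-ratio scaling (log2 change 0.27). Tnfsf14 did not pass the test (67.8 ± 9.93 against 88.1 ± 18.2 FPKM, log2 change -0.36, limma adjusted p = 0.176). With the replicate number as a block, and under median-ratio scaling (-1.18), it passed the test as lower in LPS+CPZ. Il6 was higher in LPS+CPZ (2.84 ± 0.998 against 0.53 ± 0.31 FPKM), but not past the test with a pseudocount of 5 or quantile scaling. Of 7 M2b markers, Il10, Cd86 and Il6 were higher and Tnf and Il1b lower, and under median-ratio scaling 2 were higher and 3 lower (camera adjusted p = 0.251), with a median log2 change of 0.09, a mean of -0.07 and a camera direction below the other genes.

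NF-kB components and targets were lower in LPS+CPZ than in LPS+EtOH in 23 of 28 cases, with Chuk, Ikbkb, Ikbkg and Traf2 higher (camera adjusted p = 3.96e-15, adjusted p = 0.272 with an estimated correlation). Bcl2a1b and Bcl2a1a, near-identical genes of an anti-apoptotic protein, stood at 168 ± 19.8 and 80.2 ± 4.78 FPKM in LPS+CPZ against 1194 ± 217 and 530 ± 80.2 in LPS+EtOH. Of 18 genes restraining TLR signalling 12 were lower and Cd200r1, Il10, Pdcd4 and Sigirr higher (camera adjusted p = 1.94e-07, adjusted p = 0.272 with an estimated correlation), Cish standing at 3.79 ± 0.807 against 46.9 ± 9.96 FPKM. Of 25 immediate early genes 11 were lower and Atf3, Fos and Jun higher, and 10 were lower when adjusted over the list alone (camera adjusted p = 3.71e-06, adjusted p = 0.272 with an estimated correlation). Under median-ratio scaling 17 of them were lower and 1 higher. Nr4a1, a nuclear receptor gene, stood at 30.6 ± 3.17 against 372 ± 40.8 FPKM. Of 32 interferon response genes 18 were lower and Iigp1, Mx2 and Oasl1 higher, 17 being lower when adjusted over the list alone (camera adjusted p = 1.51e-07, adjusted p = 0.713 with an estimated correlation). Among 19 inflammatory cytokines and mediators 11 were lower and 7 higher (camera adjusted p = 0.00336, adjusted p = 0.715 with an estimated correlation and 0.139 under median-ratio scaling).

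Integrated stress response genes were higher in LPS+CPZ than in LPS+EtOH in 21 of 25 cases, with Ppp1r15a lower, a call lost under quantile scaling (camera adjusted p = 0.00364, adjusted p = 0.715 with an estimated correlation). Asns, the asparagine synthetase gene, stood at 38.1 ± 6.0 against 1.66 ± 0.227 FPKM. Heat shock genes were higher in 18 of 20 cases, 19 when adjusted over the list alone (camera adjusted p = 0.000917, adjusted p = 0.715 with an estimated correlation), and glycolysis and hypoxia genes in 24 of 27, with Hif1a lower (camera adjusted p = 0.000121, adjusted p = 0.706 with an estimated correlation). Pdk1, a kinase gene that restrains pyruvate oxidation, stood at 8.06 ± 0.785 against 0.256 ± 0.0373 FPKM. B cell markers were higher in 12 of 13 cases (camera adjusted p = 0.0196, adjusted p = 0.715 with an estimated correlation), Ighm standing at 1160 ± 89.2 against 120 ± 18.2 FPKM. Neutrophil markers were lower in 11 of 13 (camera adjusted p = 4.5e-09, adjusted p = 0.272 with an estimated correlation), with Ly6g higher as deposited (274 ± 31.1 against 156 ± 12.3 FPKM) and at a log2 change of -0.02 under median-ratio scaling.

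The leading rises from LPS+EtOH to LPS+CPZ were Bnip3 (log2 change 4.99 ± 0.19), the immunoglobulin segment gene Iglj2 (4.73 ± 0.79), the scavenger receptor gene Cd36 (4.49 ± 0.23), the platelet factor 4 gene Pf4 (4.32 ± 0.29) and the carboxypeptidase gene Scpep1 (4.04 ± 0.15). Iglj2 stood at 0.0793, 12.1 and 0.102 FPKM in the LPS+EtOH libraries. The leading falls were G0s2, which encodes an inhibitor of lipolysis (log2 change -4.42 ± 0.19), Hdc, which encodes the histamine-forming enzyme (-3.94 ± 0.16), Mir142hg, the host gene of a blood cell microRNA (-3.85 ± 1.16), Ifitm6 (-3.74 ± 0.21) and the protease gene Asprv1 (-3.59 ± 0.19).

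With limma, 8980 genes changed between LPS+CPZ and LPS+EtOH, 7195 higher and 1785 lower in LPS+CPZ, around a median log2 change of 0.55. Under median-ratio scaling the median was 0.04, and 3976 genes were higher and 3863 lower. Quantile scaling gave 3844 higher and 3144 lower. On the deposited scale, with its shift of all values, the groups did not overlap for 79.0% of genes, where chance gives 10%. Chemokines, M2a markers, MAPK kinases, mitochondrially encoded transcripts, cell cycle genes, p53 targets, antigen presentation genes and large peritoneal macrophage markers had medians and means above 0 but a camera direction below the other genes. The same direction came with a median above 0 and a mean below 0 for small peritoneal macrophage markers, and with a median below 0 and a mean above 0 for MAPK phosphatases. Except where stated, the number of changed genes adjusted over the list alone equalled that over all genes tested for each list whose counts are given here.

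Both treatments were also compared through their shared reference. Against LPS, 1392 genes were higher and 4987 lower in both treated groups, Il10, Tnfsf14 and Hmox1 being among the former and Il6, Cd86 and the globin genes among the latter, and 696 genes moved in opposite directions. Independent lists of the same sizes would share 462.7 higher and 3662.6 lower genes. In 50 simulations all 9 libraries, the LPS ones included, were drawn around the LPS means without any change. These simulated groups shared 0 genes, which follows from the absence of change and does not measure sharing beyond the reference. Under median-ratio scaling 2647 genes were higher and 2850 lower in both, against 1336 and 1527.8 for independent lists. The correlation of the log2 changes across genes was 0.689, against 0.495 for simulated unchanged groups, and their covariance was 0.865, against 0.0189. The 3 LPS libraries cannot be split into sets of at least 2 each, so part of the excess over independent lists may come from the shared reference.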

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

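Leaving out the globin genes, testing protein-coding genes alone and median-ratio scaling with an estimated correlation were chosen after the data were seen, and the other alternatives before. With 5 FPKM as the filter 5345, 4741 and 4993 genes changed in LPS+EtOH against LPS, LPS+CPZ against LPS and LPS+CPZ against LPS+EtOH, and 3626 changed the same way with both treatments, fewer genes being tested. Requiring a log2 change of at least 1 left 6267, 3155 and 3665 genes and 2202 in the overlap. For LPS+EtOH against LPS 20 gene lists were called with no filter beyond a value above 0 and 17 under quantile scaling, against 11 as reported, and the cause was not tested. With an estimated inter-gene correlation 0, 0 and 0 lists were called in the 3 comparisons, and 0, 0 and 0 when median-ratio scaling was used as well. Robust fitting and the log2 threshold do not apply to the list test and were not run for it.

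Over 212 values of 149 named genes, the alternatives left 4760 results on the same side of the threshold with the same direction, ended 25 calls, added 18 and turned the sign of 10. Median-ratio scaling turned Tnf (0.54) and Il1b (0.56) in LPS+EtOH against LPS, Il12b (0.07) in LPS+CPZ against LPS, and Sphk1 (-0.36) and Ly6g (-0.02) in LPS+CPZ against LPS+EtOH, each away from the shift of all values that this scaling removes. Quantile scaling turned Il12b (0.11) and Arg1 (0.04) in LPS+CPZ against LPS, and Sphk1 (-0.53) and Mrc1 (-0.01) in LPS+CPZ against LPS+EtOH. Arg1 in LPS+CPZ against LPS also turned without LPS+CPZ replicate 2, its values without single libraries ranging from -0.83 to 0.11. The cause of these was not tested.

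Without single libraries 8768 to 9753, 6786 to 8049 and 8160 to 8634 genes changed in the 3 comparisons, 11 to 13, 13 to 14 and 15 to 16 lists were called, and 5169 to 6263 genes overlapped. With globin genes left out 10176, 8921 and 8811 genes changed, and with protein-coding genes alone 8133, 6807 and 7536.

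With the replicate number as a block (replicate block) 9871, 8156 and 9086 genes changed, 12, 13 and 15 lists were called and 6424 genes overlapped. Sphk1 in LPS+CPZ against LPS and Tnfsf14 in LPS+CPZ against LPS+EtOH then passed the test. Same-numbered LPS+EtOH and LPS+CPZ libraries share a stem in their column names, but the labels do not say what the number marks. Deviations of same-numbered libraries correlated at -0.006, 0.171 and 0.031 between LPS and LPS+EtOH, 0.26, 0.097 and 0.02 between LPS and LPS+CPZ, and 0.064, 0.142 and 0.079 between LPS+EtOH and LPS+CPZ. Those of differently numbered libraries ranged from -0.204 to 0.127. Not every library correlated best with its own number, so whether the numbers pair libraries stays open. Fragment counts were not used here, so the limit set by depth on weakly expressed genes could not be computed.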

Other observations

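Of the tests in this part, those on erythroid genes below the filter, on cells collected apart, on the scaling of neutrophil genes, on neutrophil genes in LPS+CPZ and on sequencing depth were chosen after the result was seen, and the others before. Genes and lists named here were chosen after their values were seen. Against LPS, 7566 of all 11721 tested genes fell in LPS+EtOH and 5674 in LPS+CPZ as deposited. Under median-ratio scaling 4705 and 3806 fell, and the list counts below stand beside these. Of 6 tested TRP channel genes, Mcoln1, Trpm2 and Trpv2 rose in both treated groups, Mcoln2 fell in both and Trpm4 fell in LPS+EtOH (camera adjusted p = 0.162 for LPS+EtOH and 0.064 for LPS+CPZ). Among MAPK phosphatases Dusp1 and Dusp5 rose in both, while 9 and 10 of 14 genes fell, 6 and 8 under median-ratio scaling (0.994 and 0.218). Of 10 M2c and scavenging markers 8 fell in each, 8 and 7 under median-ratio scaling, with Stab1 higher in both and Cd36 higher in LPS+CPZ (0.188 and 0.218; for LPS+EtOH 0.036 under median-ratio scaling, and 0.68 with an estimated correlation as well). Of 17 lipid targets of LXR and PPAR 14 fell in LPS+EtOH and 11 in LPS+CPZ, 10 and 5 under median-ratio scaling, and the lipid droplet gene Plin2 rose in both (0.159 and 0.371). Of 16 chemokines 9 fell in each, 8 and 7 under median-ratio scaling, while Cxcl2 and Cxcl3 rose in both (0.824 and 0.532). Of 20 heat shock genes 10 fell and Bag3, Hspa1a, Hspa1b and Hspa4l rose in LPS+EtOH, 3 of them adjusted over the list alone, and under median-ratio scaling 13 rose and 5 fell (0.408).

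Between LPS+CPZ and LPS+EtOH, TLR4 pathway genes were higher in 7 and lower in 6 of 17 cases, 7 each adjusted over the list alone, and higher in 3 and lower in 10 under median-ratio scaling (camera adjusted p = 0.0237, adjusted p = 0.272 with an estimated correlation), the lower ones being Tlr4, Cd14, Myd88, Tirap, Irak2 and Tlr2. Of 19 inflammasome genes 5 were higher and 6 lower, and 3 higher and 12 lower under median-ratio scaling (camera adjusted p = 0.0448, adjusted p = 0.272 with an estimated correlation), with a median of -0.01, a mean of 0.01 and a camera direction below the other genes. Mast cell genes Cma1, Hdc, Kit and Tpsab1 were lower and Hpgds higher (camera adjusted p = 0.00664, adjusted p = 0.715 with an estimated correlation and 0.104 under median-ratio scaling). The 4 globin genes were lower (list camera adjusted p = 0.00364, adjusted p = 0.715 with an estimated correlation and 0.0928 under median-ratio scaling), and 28 of 30 ribosomal protein genes were higher, 7 under median-ratio scaling (camera adjusted p = 0.0177, adjusted p = 0.821 with an estimated correlation and 0.144 under median-ratio scaling).

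Globin transcripts were higher in all LPS libraries than in all treated ones, the lowest LPS share being 51.9 times the highest treated share. A candidate explanation is RNA from red blood cells or their precursors in the LPS cells. Other erythroid genes lay below the median of all genes by a log2 difference of -1.08 in LPS+EtOH (-1.11 to -1.01 over the libraries) and -0.84 in LPS+CPZ (-0.87 to -0.8). The bound set beforehand, at least 1 below in each library, was thus met in LPS+EtOH only. However, only 3 genes could be tested, of which 2 fell in each group and 1, Slc25a37, rose in LPS+EtOH. The minimum of 5 genes for a verdict was set after this was seen, and it alone withholds a verdict for LPS+EtOH. With genes below the filter included, 12 of 19 were higher in every LPS library than in every LPS+CPZ library (63.2%, against 34.8% of all genes of the same LPS range). For LPS+EtOH it was 13 of 19 (68.4% against 49.4%). The margin required for this explanation was set after the result was seen, and only LPS+CPZ reached it. These tests therefore show no clear difference between the treatments. The column names call the LPS libraries controls and give same-numbered treated libraries a shared stem, but the labels give no day or batch. Whether LPS cells were collected or washed apart from the others therefore cannot be told apart from the treatment.

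Neutrophil genes were higher in LPS+EtOH. Library scaling as the cause is argued against by a list median of at least 2.72 under 4 scalings. A larger share of neutrophil RNA may contribute: of 14 other neutrophil genes 11 rose and 0 fell, with a median 2.24 above that of all genes (2.04 to 2.38 over the libraries), and S100a9 reached 33420 ± 2070 FPKM. Of these, Clec4d, Clec4e, Fpr1, Fpr2, Itgam and Anxa1 are also expressed by macrophages, so induction by ethanol within macrophages stays open and was not tested. In LPS+CPZ at least 2 list members rose and at least 2 fell under both the deposited and the median-ratio scaling, which restates the pattern and decides nothing. S100a9 stood at 3369 ± 551 FPKM in LPS and 3208 ± 99.4 in LPS+CPZ. Of the 14 other neutrophil genes 6 rose and 5 fell there. Their median log2 change was -0.02 in LPS+CPZ, against -0.33 for all genes. In LPS+EtOH these medians were 1.46 and -0.82. No rise shared by these genes was seen, but since members went both ways a larger share of neutrophil RNA stays open.

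Most genes had lower values in LPS+EtOH. The 200 most abundant genes as the whole cause are argued against. With them left out and the others rescaled, the median log2 change was still -0.62. That value is a net one, since the globin genes, abundant in LPS, are among those left out. Leaving out the globin genes alone gave 1734 higher and 8442 lower genes. A larger share taken by further genes stays open. Gene length is argued against by a median of -0.76 or lower in each of 3 equal groups of genes by length. Depth as the whole cause is argued against by a fit over all 9 libraries: with the trend over estimated depth within groups removed, the median log2 change was -0.81 ± 0.06 SE (95% CI -0.96 to -0.66), against -0.82 ± 0.05 before. The number of genes at 1 FPKM or more in the deepest LPS+EtOH library differed by -2900 from that in LPS replicate 3, but their depths of 32850000 and 31890000 fragments are too close to order these libraries. Losses among weakly expressed genes alone stay open, since genes of at least 10 FPKM had a median of -0.24 (-0.33 to -0.18 over the libraries), between the bounds set beforehand. Loss of some transcripts more than others under ethanol may also contribute and was not tested. An even loss of RNA would not lower FPKM, which is relative to the fragments of each library.

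The 10 splits of 6 libraries are too few for a share under 0.05. The real splits called 9796, 8106 and 8980 genes and the highest other splits 0, 1 and 1, the real value being reached in 1 split each. Every other split mixes libraries of both groups and so puts their difference into the spread. Few calls there were fixed in advance, and the contrast shows only that the groups differ. For gene lists the real splits called 11, 13 and 15 and the highest others 17, 19 and 15, and the real number was reached in 7, 7 and 2 splits. In the comparisons with LPS the number of lists called therefore does not set the real groups apart from mixed ones. The list p-values with the preset correlation are limited by this. The overlap of both treatments (6379 genes) was reached in 2 of 100 drawn regroupings, the real grouping included. The other was the 3 groups kept whole with LPS+EtOH as the shared reference (7254), and the highest of those that break up the groups was 5553. Breaking up the groups mixes their difference into the spread, so a low share follows from the groups differing. It says nothing about sharing beyond the shared reference.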
